A study of Mus musculus with 36 samples.

How the data were processed

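Messenger RNA of primary mouse cortical astrocyte cultures was measured on Illumina bead arrays, 1 labelled cRNA sample per array. The labels place 36 arrays in 12 groups of 3: vehicle, 100 nM corticosterone, 500 nM RU486, or both, each for 2, 4 or 6 h. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. GenomeStudio is named in the submitters' processing notes, with no version. The growth protocol in the labels speaks of cortex or hippocampus, and the samples themselves are called cortical.

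The authors deposited a value table of 45281 probes whose values are linear intensities. From the values, the columns had been quantile-normalized: the sorted columns differ by at most 1.15%, and the array medians lie between 110.5 and 111.2. No background had been subtracted, so fold changes of dim genes are understated. A further table holds 36 signal columns and as many of detection p-values. Its 72 columns of per-sample values carry numbers that match no label, so they were not used. Of that table, probe identifiers and gene symbols alone were read. For this reason neqc, its offset, the filters on detection p-values and the bead chip as a block, all fixed before the data were examined, were not run. The number of arrays limits the precision.

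The intensities were put on the log2 scale. Probes brighter than their array's median on at least 3 arrays were kept, which left 28397. Each gene was represented by its brightest probe over all 36 arrays, giving 18935 genes. Of these, 11396 names were current in the RefSeq gene table of assembly GRCm38.p6, 3040 were updated through a synonym, and 4499 kept the name of the file. A linear model with 12 group means and no covariate was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors of fold changes are the standard errors (SE) of that fit. Mean contrasts average the 3 times. The interaction compares the corticosterone effect with and without RU486. Changes of vehicle over time were tested with limma's F test.

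18 gene lists with 281 distinct genes, 245 of them measured, were fixed before the data were examined and tested with camera at a preset correlation of 0.01. The lists overlap in a few genes, such as Per1 and Fkbp5. A list needed at least 5 measured members. The adjustment ran over lists and times within each kind of comparison. Steroid-response genes for 1 time were those called at either of the other 2 times, and their signed shift was tested with limma's fry, adjusted over the 3 times within each kind of comparison. The genes named are, for corticosterone against vehicle at each time, the 8 highest and 6 lowest called genes whose groups did not overlap. For other comparisons they are the 4 highest and 4 lowest, with no overlap condition for means and interactions. Members of the lists are also named, and predicted genes and clones are not. Not every gene that meets this rule is named. Each named value rests on the gene's brightest probe, and its other, dimmer probes were not always called when tested separately. Plots were drawn with matplotlib 3.10.9.

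The fit gives every array the same weight, although the arrays differ in noise. The procedure was tested on simulated data with each array's own noise and 18935 genes. With no gene changed, the share of unadjusted p-values under 0.05 at 6 h was 22.8% for corticosterone, 22.9% for RU486 and 36.2% for both, each against vehicle. It was 0.196% for corticosterone against vehicle at 4 h. No false call was made in those 4 comparisons after adjustment. Without the 2 arrays that stand apart, equal weights gave at 2 h a median of 52 false calls for RU486 against vehicle, 30 for both against vehicle and 3.5 for corticosterone against vehicle, so those 3 counts may hold false calls. The median was 0 for the other comparisons. With array weights and all arrays, the share was 4.47% for corticosterone against vehicle at 6 h and 4.19% at 4 h. With no shift, fry gave p under 0.05 for RU486 against vehicle in 2 of 20 simulations at 2 h and 3 of 20 at 6 h, and without the 2 arrays in 4 of 20 at 2 h and 0 of 20 at 6 h. The simulation draws genes independently, which real arrays do not. For corticosterone against vehicle at 4 h, 17.6% of genes changed by 0.5 on the log2 scale, 62.1% of those changed by 1 and 92.4% of those changed by 2 were recovered. Array weights were estimated gene by gene, because the default method did not converge, and the weighted counts stand beside the main ones.

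Alternatives were the filter, all probes separately, normexp with an offset of 16 or 50, only the groups compared, a replicate block, array weights, an intensity trend with robust prior, each array left out, an estimated correlation for camera, and the choice of response genes. Normexp, the brightness filters, the fits without the 2 arrays, their combination with weights, the single-time counts of both against RU486 and the fit of only the groups compared with unchanged response genes were chosen after seeing the data.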

Results

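Corticosterone is the main glucocorticoid of rodents, and RU486 (mifepristone) is an antagonist of the glucocorticoid receptor. Astrocyte cultures from newborn mice were treated with vehicle, 100 nM corticosterone, 500 nM RU486, or both, and sampled at 2, 4 and 6 h, with 3 arrays in each of the 12 groups. The fit held 18935 genes, each brighter than the array's median on at least 3 arrays. Of the 36 arrays, 34 had a median correlation of 0.960 to 0.990 with the others. Vehicle 6 h replicate 1 had 0.757, and corticosterone with RU486 6 h replicate 3 had 0.886. The counts of genes called in each comparison are therefore followed by those without these 2 arrays and those with array weights and all arrays.

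**Figure D1:**
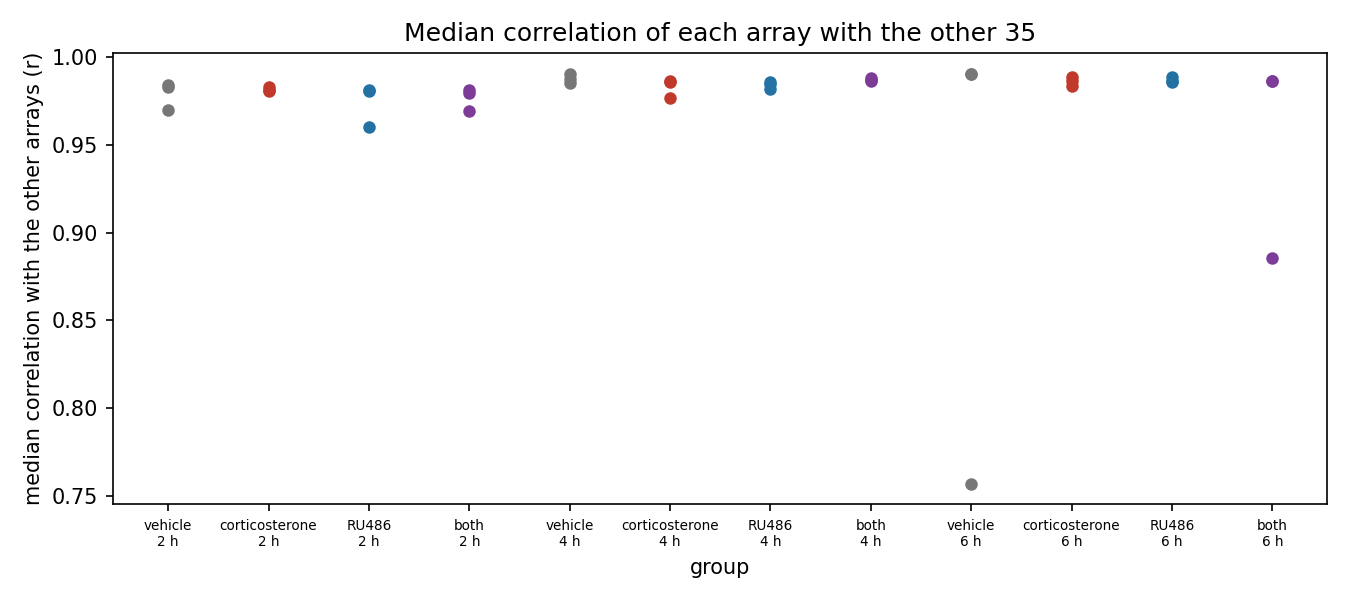
Median Pearson correlation (r, y axis) of each array with the other 35, by group (x axis), 1 point per array. 34 arrays lie between 0.960 and 0.990, and 1 vehicle array at 6 h (0.757) and 1 array of both compounds at 6 h (0.886) lie below.

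The first comparison asked which genes corticosterone changed within 2 h. Fam107a, an actin-associated protein, rose most, by 2.23 on the log2 scale (SE 0.31, limma adjusted p = 0.000499). Sgk1, a kinase that regulates ion transport, rose by 1.81 (SE 0.15), as did Tsc22d3, also called GILZ, by 1.81 (SE 0.29). Fkbp5, a chaperone of the receptor, rose by 1.65 (SE 0.25), the transcription factor Klf9 by 1.57 (SE 0.29) and Pdk4, an inhibitory kinase of pyruvate dehydrogenase, by 1.57 (SE 0.22). Bcat1, which transaminates branched-chain amino acids, rose by 1.5 (SE 0.24) and the small heat shock protein Hspb1 by 1.26 (SE 0.26). Klf9 and Hspb1 kept their call in 2 and 1 of the 6 fits that leave out 1 of these arrays. Tested separately, the other probe of Tsc22d3 was called too, while those of Klf9 and Pdk4 were not. In all, 23 genes were called, 22 higher and 1 lower. The count was 128 without the 2 arrays, 81 higher and 47 lower, and 225 with array weights.

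At 4 h Fam107a was higher by 3.49 (SE 0.31), Fkbp5 by 2.88 (SE 0.25), Tsc22d3 by 2.41 (SE 0.29), Pdk4 by 2.27 (SE 0.22) and Bcat1 by 2.19 (SE 0.24). Folh1, a glutamate carboxypeptidase, rose by 2.17 (SE 0.35), the proline dehydrogenase Prodh by 2.14 (SE 0.28) and the sulfotransferase Sult1a1 by 2.10 (SE 0.29). Lower genes included the lysosomal lipase Lipa (-1.48, SE 0.34), Phlda1 (-1.42, SE 0.25), the sphingosine phosphate lyase Sgpl1 (-1.04, SE 0.24), the phosphodiesterase Pde1b (-1.01, SE 0.17), the diacylglycerol kinase Dgkg (-1.0, SE 0.17) and Mex3a (-0.97, SE 0.23). Lipa, Sgpl1 and Mex3a lost their call in each of the 6 fits that leave out 1 of these arrays. Another probe was called the same way for Tsc22d3, Prodh and Pde1b. For Pdk4, Lipa, Sgpl1, Dgkg and Mex3a no other probe was called. The test called 157 genes, 86 higher and 71 lower. It called 1672 without the 2 arrays, of which 611 were higher, and with array weights 6329.

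At 6 h Fam107a was higher than in vehicle by 4.74 (SE 0.31), and by 4.17 without the 2 arrays. Its mean log2 intensity was 12.60 ± 0.003 (SD, n = 3) against 7.86 ± 0.98 (SD, n = 3). The SE pools the spread of all 12 groups, and so does not show the wide spread of vehicle here. Fkbp5 rose by 3.10 (SE 0.25), Pdk4 by 2.60 (SE 0.22), Bcat1 by 2.58 (SE 0.24) and Lcn2, lipocalin 2, by 2.52 (SE 0.24). Slc25a33, a mitochondrial nucleotide carrier, rose by 3.27 (2.35 without the 2 arrays), the small GTPase Rhou by 2.69 (1.92) and the clock gene Per1 by 2.58 (1.82). Tnfrsf11b, a decoy receptor for RANKL, fell by 1.86 (-1.22 without the 2 arrays), Phlda1 by 1.51 (-1.14), the prokineticin receptor Prokr1 by 1.37 (-0.64) and the neurotrophin Bdnf by 1.22 (-0.70). The calls of Ch25h, cholesterol 25-hydroxylase (-1.25), and Ldb2 (-1.24) were lost without the 2 arrays, at adjusted p = 0.219 and 0.102. Prokr1, Ch25h and Ldb2 each kept their call in 2 of 6 fits with 1 array left out, and Per1 and Bdnf in 3. Of the other probes, 1 of 2 was called for Per1, 0 of 3 for Bdnf and 0 of 1 each for Pdk4, Prokr1 and Ldb2. The test called 191 genes, 138 higher and 53 lower. The count was 295 without the 2 arrays, with 155 genes shared, and 1659 with array weights. It was 4682 without vehicle 6 h replicate 3 and 3695 without vehicle 6 h replicate 2. Those fits keep vehicle 6 h replicate 1, which stands apart, beside 1 other vehicle array.

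**Figure D2:**
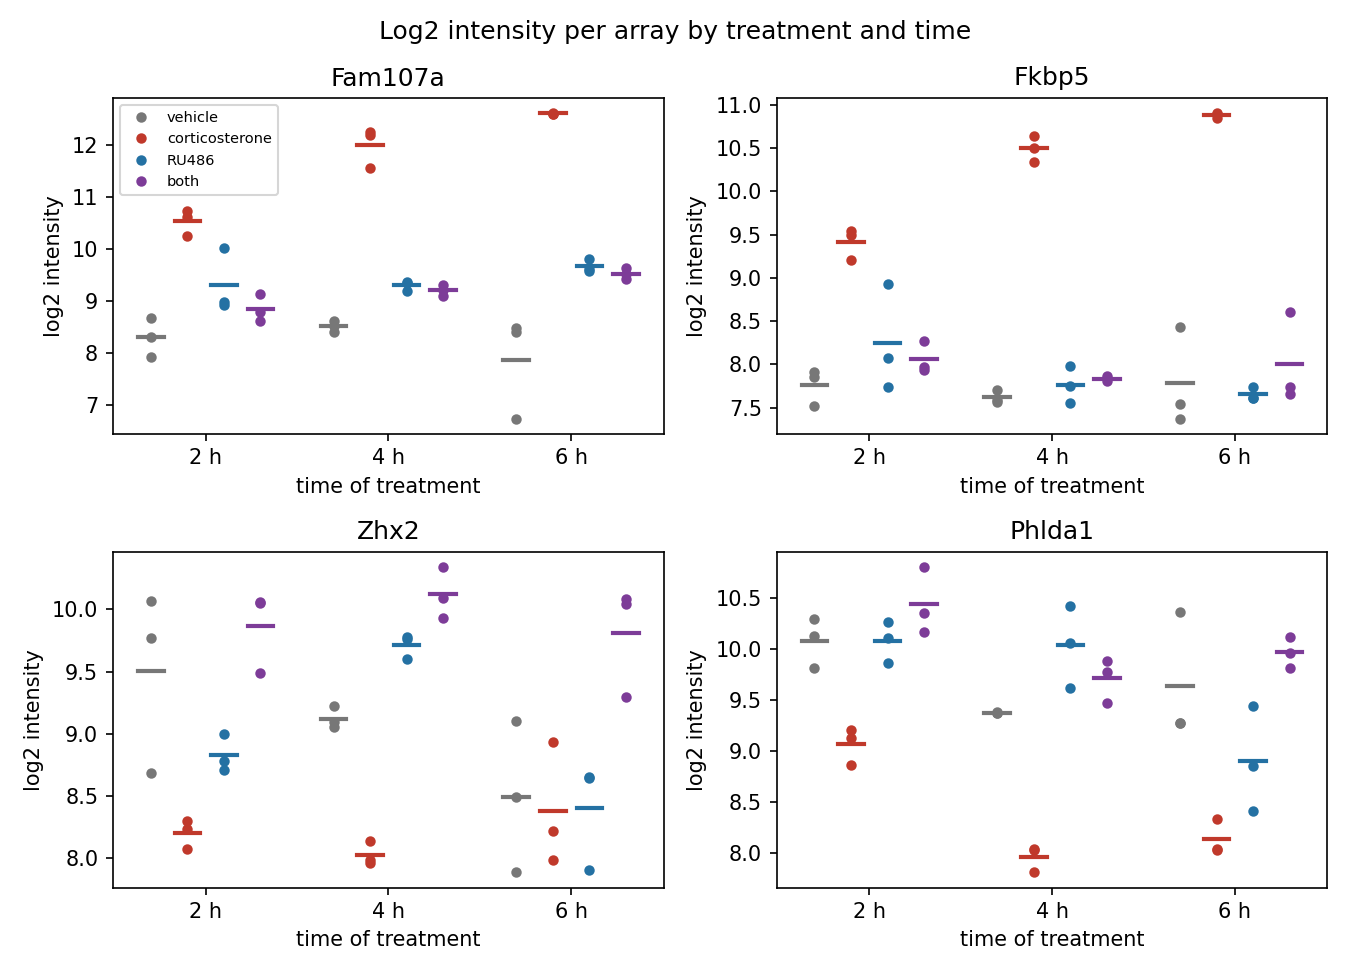
Log2 intensity (y axis) of Fam107a, Fkbp5, Zhx2 and Phlda1 on each array (points) with group means (lines), by treatment and time (x axis, h). Fam107a reaches a mean of 12.60 with corticosterone at 6 h, against 7.86 in vehicle and 9.51 with both compounds.

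The 3 times share no arrays. Of the 22 genes higher at 2 h, 21 were also higher at 4 h, where independent lists would share 0.10, and 21 at 6 h, where they would share 0.16. The 4 h and 6 h lists shared 61 higher genes (0.63 for independent lists) and 14 lower genes (0.20). In all, 20 genes were called at every time, among them Fam107a, Fkbp5, Klf9, Sgk1, Tsc22d3, Zbtb16, Bcl6, Errfi1 and Csrnp1. Averaged over the times, 560 genes were called, 281 higher and 279 lower. That count was 2352 without the 2 arrays, 962 higher and 1390 lower, and 5197 with array weights. Fam107a (3.48, SE 0.18), Fkbp5 (2.54, SE 0.14), Per1 (2.20, SE 0.32) and Pdk4 (2.15, SE 0.13) led the higher genes. Lbh (-1.52, SE 0.28), Phlda1 (-1.31, SE 0.14), Lipa (-1.06, SE 0.20) and Tnfrsf11b (-1.01, SE 0.21) led the lower ones.

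The size of the corticosterone effect was compared between times. Between 6 h and 2 h limma called 11 genes, all larger at 6 h. Fam107a differed by 2.51 (SE 0.43) and the tight junction gene Cldn2 by 2.00 (SE 0.36), or by 1.95 and 1.40 without the 2 arrays. Lcn2 differed by 1.89 (SE 0.35) and the kinase Mapk4 by 1.71 (SE 0.25). Cldn2 and Lcn2 kept their call in 5 of 12 fits with 1 array left out. Between 4 h and 2 h, 1 gene differed, listed as Tilz3c (0.996, SE 0.15) and named here after its value was seen, and between 6 h and 4 h limma called 0, with 1338 at an unadjusted p under 0.05. These counts were 41, 5 and 0 without the 2 arrays and with array weights 119, 24 and 684.

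The list of genes known to be induced by glucocorticoids rose at every time. Of its 20 measured members, 7 rose at 2 h, 9 at 4 h, 13 at 6 h and 14 over the times, and none fell. Adjusted over the list alone, 11, 14, 14 and 15 rose. Over all genes tested, 12, 15, 15 and 16 rose without the 2 arrays. The median log2 change was 0.71, 0.82 and 1.19 at 2, 4 and 6 h. The camera test gave adjusted p = 5.22e-30, 1.62e-31 and 5.06e-23, and the calls hold with an estimated correlation (adjusted p = 6.47e-06, 6.13e-06 and 4.21e-05). The transcription factor Zbtb16 rose by 0.96 at 2 h (SE 0.16) and Mt2, a metallothionein, by 1.26 at 6 h (SE 0.29). Mt1 (-0.02, SE 0.10 at 6 h) did not pass.

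The inflammatory cytokine and chemokine list was lower at 2 h (median -0.22, adjusted p = 0.0022), with adjusted p = 0.0438 with an estimated correlation. The latter was 0.112 without the 2 arrays, and the preset correlation gave 0.0759 without vehicle 2 h replicate 1. It was also lower at 4 h and over the times, where adjusted p = 0.0855 and 0.0668 with an estimated correlation. None of its 15 measured members passed over all genes tested at a single time, and adjusted over the list alone 2 were lower at 4 h. Without the 2 arrays, 1 member was lower at 2 h, 4 at 4 h and 1 at 6 h. For Ccl2, a chemokine, the change at 2 h was -0.19 (SE 0.12). Cholesterol synthesis genes were lower at 2 h (median -0.16) and 4 h (median -0.30), with adjusted p = 0.27 and 0.148 with an estimated correlation and 0 of 15 members called. The cholesterol list without the 2 arrays was lower at 4 h, 6 h and over the times also with an estimated correlation (adjusted p = 0.00472, 0.000327 and 0.000845), with 4, 1 and 7 members lower. Growth factor genes were lower at 2 h (median -0.02), with adjusted p = 0.0668 with an estimated correlation. In that list, at 6 h, Bdnf was lower while Ntf3, neurotrophin 3, was higher by 0.74 (SE 0.14). Clock genes were higher at 2 h (median 0.13, adjusted p = 0.0668 with an estimated correlation), with 0 of 14 members called. This was 0.0197 without the 2 arrays, with 2 members higher.

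Astrocyte markers were higher at 6 h (median 0.33) and over the times, with adjusted p = 0.0855 and 0.133 with an estimated correlation. In this list the gap junction gene Gjb6 rose by 1.80 (SE 0.30) and Ndrg2 by 0.98 (SE 0.18), and Gfap was at 0.55 (SE 0.64). Neuron markers were lower at 4 h (median -0.26) and over the times (median -0.19), with adjusted p = 0.339 and 0.325 with an estimated correlation. Glucose and glycogen genes, extracellular matrix genes and cell cycle genes were higher at 6 h, with adjusted p = 0.14, 0.326 and 0.133 with an estimated correlation. Vehicle 6 h replicate 1 moves with these 3 lists, and without the 2 arrays their adjusted p was 0.981, 0.877 and 0.0226. Glucose and cell cycle genes were also higher over the times, where adjusted p = 0.325 and 0.414 with an estimated correlation. Astrocyte markers without the 2 arrays had adjusted p = 0.0843 at 6 h and 0.129 over the times, and over the times neuron markers had 0.142, glucose genes 0.885 and cell cycle genes 0.728. Over the times and with all arrays, the lists that did not pass were immediate-early (adjusted p = 0.334), reactive astrocyte (0.938), clock (0.0951), cholesterol (0.0951), stress response (0.111), extracellular matrix (0.135), growth factor (0.111) and steroid receptor and chaperone genes (0.395). Markers of microglia (0.814), oligodendrocyte lineage (0.34), endothelium (0.466) and fibroblasts or meninges (0.395) did not pass either.

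RU486 alone was compared with vehicle to see what the antagonist does without added steroid. Averaged over the times, Fam107a was higher by 1.20 (SE 0.18, limma adjusted p = 0.00511), as were the RNA-binding protein Taf15 (0.74, SE 0.12), Pogk (0.46, SE 0.08) and Zfp180 (0.30, SE 0.06). The sterol carrier Stard4 was lower (-0.87, SE 0.15), with the zinc finger protein Zfp148 (-0.76, SE 0.14), Arhgap32 (-0.74, SE 0.15) and Dgkg (-0.48, SE 0.10). Zfp180, Arhgap32 and Dgkg kept their call in 7, 6 and 9 of the 18 fits that leave out 1 array. These are among 14 genes called, 5 higher and 9 lower. At single times limma called 0 genes at 2 h, with 1340 at an unadjusted p under 0.05, and 0 at 6 h, with 4108. In simulations with no gene changed, 22.9% of the 18935 genes had such a p at 6 h, which is more than 4108, and 4.88% at 2 h. At 4 h limma called 1, the repair protein Rad23b (1.28, SE 0.18), with 1197 at an unadjusted p under 0.05. The simulated share at 4 h was 0.239%, so the test was strict there and a small count does not show that nothing changed. No call was made for the 3 other probes of Rad23b. Rad23b kept its call in 4 of 6 fits with 1 array left out, and the count ranged from 0 to 22. Without the 2 arrays the counts were 603, 759 and 0 at 2, 4 and 6 h and 282 over the times, 139 of these higher, and with array weights 387, 6377, 356 and 1827. At 6 h it called 5330 without vehicle 6 h replicate 3 and 4170 without vehicle 6 h replicate 2. Each of these fits keeps vehicle 6 h replicate 1, which stands apart.

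With RU486 alone, glucocorticoid-induced genes were higher at 2 h (median 0.20) and over the times (median 0.09), with adjusted p = 0.48 and 0.366 with an estimated correlation and 0 of 20 members called. Immediate-early genes were higher at 2 h (median 0.31) and over the times (median 0.11), with adjusted p = 0.131 and 0.366 with an estimated correlation. Reactive astrocyte genes were higher at 2 h (median 0.14, adjusted p = 0.366 with an estimated correlation, and 0.0757 without the 2 arrays at the preset one). Cell cycle genes were lower at 2 h (median -0.34) and higher at 6 h (median 0.56), both at adjusted p = 0.366 with an estimated correlation. Glucose and glycogen genes were higher at 6 h (median 0.27) and over the times (median 0.19), and extracellular matrix genes over the times (median 0.18), all 3 at adjusted p = 0.366 with an estimated correlation. Vehicle 6 h replicate 1 moves with these 2 lists and, as said above, with the cell cycle list. Without it the glucose list had adjusted p = 0.869 at 6 h and 0.252 over the times, and the matrix list 0.302 over the times. Without the 2 arrays, the glucocorticoid-induced list over the times had adjusted p = 0.0477 with an estimated correlation and 3 members higher, and cholesterol genes were lower at 6 h (median -0.28, adjusted p = 9.65e-05 with an estimated correlation).

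RU486 and corticosterone, both steroids, were given at different doses, 500 and 100 nM. Averaged over the times, RU486 lay below corticosterone for Fkbp5 (-2.38, SE 0.14), Fam107a (-2.28, SE 0.18), and Tsc22d3 and Bcat1 (-1.96 each, SE 0.16 and 0.14). It lay above for Lbh (1.54, SE 0.28), Phlda1 (1.29, SE 0.14), Tomm6 (1.02, SE 0.22) and Arl4c (1.00, SE 0.27), which kept its call in 2 of the 18 fits that leave out 1 array. The test called 406 genes, 208 higher and 198 lower with RU486. The count was 2330 without the 2 arrays, 1441 of them higher, and 5042 with array weights.

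Adding RU486 to corticosterone lowered the induced genes. At 2 h Fam107a was lower with both compounds than with corticosterone (-1.69, SE 0.31), as were Klf9 (-1.64, SE 0.29), Tsc22d3 (-1.63, SE 0.29) and Sgk1 (-1.53, SE 0.15). At 4 h the lowest were Fam107a (-2.79, SE 0.31), Fkbp5 (-2.66, SE 0.25), Prodh (-2.22, SE 0.28) and Bcat1 (-2.07, SE 0.24). At 6 h they were Fam107a (-3.09, SE 0.31), Fkbp5 (-2.88, SE 0.25), Per1 (-2.45, SE 0.55; -1.37 without the 2 arrays) and Prodh (-2.41, SE 0.28). Genes higher with both were the transcriptional repressor Zhx2 (1.66, 2.09 and 1.43 at 2, 4 and 6 h), Lbh (2.70 at 4 h and 2.24 at 6 h), the mitochondrial import subunit Tomm6 (1.62 at 2 h), the proteasome activator Psme3 (1.57 at 2 h), Selenow (1.51 at 2 h), Bcl9l (2.12 at 4 h) and Phlda1 (1.83 at 6 h). With 1 array left out, Tomm6 and Psme3 at 2 h and Bcl9l at 4 h kept their call in 1, 2 and 1 of 6 fits, and Per1 at 6 h in 3. The test called 148, 597 and 265 genes at 2, 4 and 6 h, and 2434 over the times, 1392 higher and 1042 lower. Without the 2 arrays the counts were 1947, 3438, 847 and 5906, and with array weights 2708, 8353, 6132 and 9109.

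Of the 20 glucocorticoid-induced genes, 7 were lower with both than with corticosterone at 2 h, 11 at 4 h, 10 at 6 h and 16 over the times, where 1 was higher. Adjusted over the list alone, 12, 14, 15 and 16 were lower. The camera test gave adjusted p = 6.36e-15, 1.36e-18 and 1.66e-27 at 2, 4 and 6 h, and the calls hold with an estimated correlation (adjusted p = 0.000888, 0.000258 and 3.46e-05). Inflammatory genes were higher at 2 h (median 0.28, adjusted p = 0.136 with an estimated correlation) and cholesterol synthesis genes at 4 h (median 0.24, adjusted p = 0.335 with an estimated correlation). Neuron markers were higher at 6 h (median 0.35) and over the times (median 0.19), and cell cycle genes lower at 6 h (median -0.21), with adjusted p = 0.335, 0.562 and 0.562 with an estimated correlation. Without the array of both compounds that stands apart, replicate 3 at 6 h, the neuron list had adjusted p = 0.178 at 6 h and 0.187 over the times, and the cell cycle list 0.626. Gfap was higher with both over the times by 1.53 (SE 0.37).

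The interaction asks whether the corticosterone effect differs with RU486 present. It was negative for Fam107a (-3.72, SE 0.25, limma adjusted p = 1.13e-10), Per1 (-2.63, SE 0.45; -2.01 without the 2 arrays), Fkbp5 (-2.47, SE 0.20) and Sult1a1 (-2.27, SE 0.24). It was positive for Lbh (2.23, SE 0.39), Zhx2 (1.79, SE 0.24), Phlda1 (1.68, SE 0.20) and the cadherin Celsr2 (1.62, SE 0.29). In all, 1130 genes were called, 629 positive and 501 negative. The count was 3881 without the 2 arrays and 7071 with array weights.

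Cells given both compounds were also compared with vehicle and with RU486 alone. Over the times, Tmem176a (1.21, SE 0.19), Nkx2-2 (1.02, SE 0.19), Fam107a (0.96, SE 0.18) and Tomm6 (0.95, SE 0.22) were higher than in vehicle, and Rab5b (-0.96, SE 0.21), Arhgap32 (-0.80, SE 0.15), Zfp148 (-0.69, SE 0.14) and Ptpn1 (-0.68, SE 0.15) were lower. Tomm6, Rab5b and Ptpn1 kept their call in 6, 9 and 7 of the 18 fits that leave out 1 array. 97 genes were called, 81 higher and 16 lower, and 1233 without the 2 arrays, 723 higher and 510 lower, and 4605 with array weights. No list passed over the times, and glucocorticoid-induced genes had a median of 0.04 (adjusted p = 0.194, and 0.0498 without the 2 arrays). At 6 h, 8 genes were called, led by Fam107a (1.65), Htra3 (0.84), Rplp2 (0.79) and Rrm1 (0.76), and 0 without the 2 arrays. Rplp2 kept its call in 3 of 6 fits with 1 array left out, and the other 3 genes in 2. Limma called 0 genes at 2 h and 0 at 4 h, with 927 and 736 at an unadjusted p under 0.05. In simulations with no gene changed, 4.13% and 0.0190% of the genes had such a p. The test was thus strict at 4 h, and the 0 there does not show that nothing changed. Without the 2 arrays the counts at 2 h and 4 h were 1 and 105, and with array weights they were 1, 6425 and 3460 at 2, 4 and 6 h. At 6 h the count was 1505 without vehicle 6 h replicate 3, 336 without vehicle 6 h replicate 2, and 0 without any 1 array of both compounds. The fits with 1505 and 336 keep vehicle 6 h replicate 1, which stands apart. Against RU486 alone, 8 genes were called over the times, among them Zhx2 (0.95, SE 0.17), Btrc (0.60), Pou2f1 (0.57) and Xpr1 (0.50) higher and Taf15 (-0.67) and Stk40 (-0.49) lower. That count was 581 without the 2 arrays, 315 of them higher, and 4868 with array weights. Of the 18 fits that leave out 1 array, Xpr1 and Stk40 kept their call in none, Taf15 in 4, Zhx2 and Pou2f1 in 5 and Btrc in 7. No call was made for the other probes of Btrc (3), Pou2f1 (4), Xpr1 (5) and Stk40 (1). At single times limma called 0 genes at 2 h, with 1532 at an unadjusted p under 0.05, 0 at 4 h, with 78, and 112 at 6 h, 103 of them higher with both. They were 807, 0 and 386 without the 2 arrays and with array weights 2274, 148 and 5763. The simulated share for this comparison at 4 h was 0.101%, so the test was strict there too. The 112 became 0 without RU486 6 h replicate 1, 2 without RU486 6 h replicate 2 and 17 without replicate 3 of both compounds.

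The steroid-response genes chosen at the other times give what is left of the response. For the 158 genes at 6 h, the median shift in the direction of the corticosterone response was 0.63 with corticosterone, 0.15 with RU486 alone (limma fry, adjusted p = 0.00785), -0.05 with both against vehicle and -0.20 with both against RU486 alone (adjusted p = 0.000771). For the 273 genes at 2 h these medians were 0.33, 0.16 (adjusted p = 0.00902), 0.03 and -0.12 (adjusted p = 0.0211). For the 193 genes at 4 h they were 0.59, 0.08 (adjusted p = 0.273), 0.06 (adjusted p = 0.524) and -0.01 (adjusted p = 0.926). On the same 193 genes without the 2 arrays, RU486 and both passed against vehicle, at adjusted p = 0.00468 and 0.026, and with genes chosen anew they did not. The ratio of both minus RU486 alone to corticosterone minus vehicle was -0.36, -0.01 and -0.32 at 2, 4 and 6 h. At 2 h and 6 h the ratio was -0.87 and -0.95 without the 2 arrays and with response genes chosen anew. It was -0.68 and -1.13 with array weights, and -1.04 and -2.85 when only the groups compared were fitted. Each of these settings chose other and more genes. The ratios are therefore not like for like, and the size of the ratio is not settled. The shifts of RU486 and of both against vehicle share the vehicle arrays, and the shift of RU486 and the difference of both from RU486 share the RU486 arrays with opposite sign. Fitted on only the groups compared, with response genes chosen in those fits, the shift of RU486 passed at 4 h. It was 0.08 at 2 h and 0.01 at 6 h, and neither passed. The 4 h genes there come from the calls at 2 h and 6 h, far fewer than the 193. Those for 2 h and 6 h come mostly from the calls at 4 h, far more than the 273 and 158. Equally, without the 2 arrays the shift of RU486 alone at 2 h was 0.09 (adjusted p = 0.149) and at 6 h 0.17 (adjusted p = 0.0726), with response genes chosen anew. These were 1744 and 1705 genes, mostly called at 4 h, whose corticosterone medians were 0.22 and 0.25. The shift at 2 h was -0.03 without vehicle 6 h replicate 2 and -0.04 without vehicle 6 h replicate 3, and the ratio was 1.66 and 6.35. In those 2 fits vehicle 6 h replicate 1, which stands apart, is 1 of 2 vehicle arrays at 6 h. The 6 h calls, from which genes for 2 h are drawn, then number 3695 and 4682. These values thus rest on another set of genes.

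**Figure D3:**
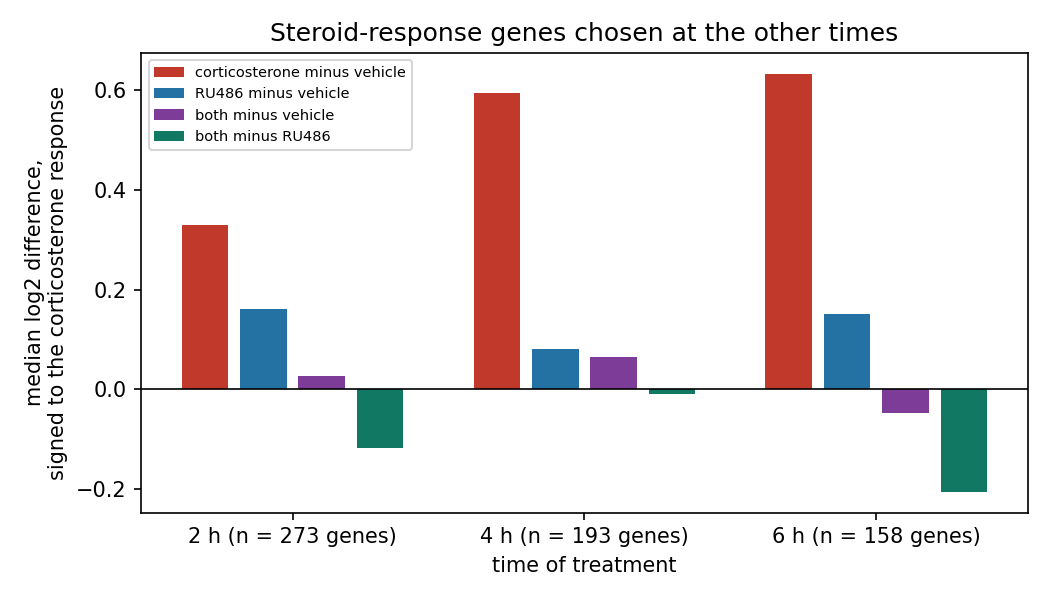
Median log2 difference, signed to the corticosterone response (y axis), of steroid-response genes chosen at the other times, by time (x axis, h), 1 bar per comparison. At 6 h the bars are 0.63 for corticosterone, 0.15 for RU486, -0.05 for both and -0.20 for both minus RU486.

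Vehicle cultures were compared over the times. The F test called 1990 genes, 3130 without the 2 arrays and 5561 with array weights, and 0 when only the vehicle arrays were fitted. Time after treatment and any culture or chip that goes with it cannot be separated by these labels.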

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

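The tests of probe pairs, of a swap, of the RU486 shift, of the weighted counts and of other splits were chosen after the result was seen, except the splits for both against RU486 at single times.

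The corticosterone effect differed with RU486 present in 1130 genes, by the test of the interaction. The values were 2.23 for Lbh, 1.79 for Zhx2, 1.68 for Phlda1 and 1.62 for Celsr2. They were -3.72 for Fam107a, -2.63 for Per1, -2.47 for Fkbp5 and -2.27 for Sult1a1. Tests of the difference between times called 11 genes between 6 h and 2 h and 1 between 4 h and 2 h. Whether chance gives such counts is not settled, because the splits described below mix corticosterone with vehicle. The values between 6 h and 2 h were 2.51 for Fam107a, 2.00 for Cldn2, 1.89 for Lcn2 and 1.71 for Mapk4.

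Vehicle 6 h replicate 1 and corticosterone with RU486 6 h replicate 3 stand apart from the other 34 arrays, and their deviations from their group mates correlate at 0.80 across genes. A swap alone, of arrays of usual quality, is argued against by their highest correlation outside their groups, 0.912 and 0.913. The other 34 arrays each reach at least 0.979. A swap together with poor quality cannot be seen in this test, because such an array would correlate less with every array. That includes a swap of these 2 arrays with each other. RNA of another cell type was tested with 5 marker lists, and none had a median deviation over 1 on both arrays, the bar set. The 8 neuron markers were at 0.42 and 0.54 and endothelial markers at 0.21 and 0.26, while the other lists were not raised on both. This argues only against a sample made up mostly of 1 of these cell types. No background was subtracted, so folds of dim genes are understated, and a partial admixture could miss that bar and stays open. Loss of part of the transcripts remains open. Across 6148 genes with at least 2 probes, the deviations of a gene's 2 brightest probes correlated at 0.30 and 0.32, within the 0.169 to 0.551 of the other 34 arrays. Deviations on these 2 arrays were larger (SD 1.48 and 1.08, against at most 0.78 elsewhere), so the values are not like for like. For comparison, the corticosterone effects of 2 probes correlated at 0.73 across 266 response genes. This decides neither way. No biological explanation was tested for a single array.

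In steroid-response genes, RU486 alone lay on the corticosterone side of vehicle at 6 h, by a median of 0.15. The 2 arrays are not the whole cause, since the median of the same 158 genes without them was 0.18 (limma fry, adjusted p = 0.0022). However, with genes chosen anew without them, 1705 in number, it was 0.17 and did not pass (limma fry, adjusted p = 0.0726). Nor is a quality trend shared with them the whole cause, since the median was 0.18 with that score as a covariate (adjusted p = 0.00106). Fitted on only the groups compared, the shift was 0.011 with response genes chosen in those fits, which does not pass, and 0.15 with the same 158 genes, so it depends on the choice of genes. Weak activation of the receptor by RU486 remains open: both against vehicle, which uses no array of RU486 alone, was at -0.047 at 6 h (adjusted p = 0.524), while at 4 h without the 2 arrays both and RU486 alone, which share the vehicle arrays, were at 0.065 and 0.081 on the same genes (adjusted p = 0.026 and 0.00468).

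With array weights, 6377 genes were called for RU486 alone against vehicle at 4 h, against 1 with equal weights. The same setting called 6329 for corticosterone and 6425 for both compounds, which share the vehicle arrays, and 8353 for both against corticosterone, which do not use them. For both against RU486 at 4 h it called 148. Something other than treatment that the 3 arrays of a group share, such as a culture or a chip, could give such counts. It cannot be told apart from treatment, because the labels name neither, and these weighted counts are therefore no measure of how many genes respond.

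Other splits of the same arrays were counted as well. For comparisons at 1 time there are 10 splits, too few for a share under 0.05. The real split gave as many genes or more in 1 of them for corticosterone against vehicle (23, 157 and 191 genes at 2, 4 and 6 h, highest other 1, 0 and 121) and for both against corticosterone (148, 597 and 265, highest other 0, 0 and 3). For RU486 against vehicle the counts were 0, 1 and 0, reached in 10, 1 and 10 splits (highest other 8, 0 and 1). For both against RU486 they were 0, 0 and 112, reached in 10, 10 and 1 splits (highest other 1, 0 and 0). For both against vehicle they were 0, 0 and 8, reached in 10, 10 and 5 splits. There the highest other was 3, 0 and 10487. At 6 h each of these groups holds 1 of the arrays that stand apart, whose deviations correlate at 0.80. Another split can place both of those arrays on the same side.

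Over the times, 100 splits were drawn. Few of them, the real one included, called as many genes for corticosterone against vehicle (560 genes, 2 splits, highest other 1749), RU486 against vehicle (14, 1 split, highest other 0) and both against vehicle (97, 2 splits, highest other 7513). The same holds for both against corticosterone (2434, 1 split, highest other 2), both against RU486 (8, 1 split, highest other 0), RU486 against corticosterone (406, 1 split, highest other 79) and vehicle over time (1990, 2 splits, highest other 3269). For the interaction (1130, 1 split, highest other 0) the splits mixed all treatments, so treatment effects entered the spread within groups. Those splits therefore cannot test the interaction by itself. Some splits call several times the real count, 1749 and 7513. Those comparisons hold 1 or both of the arrays that stand apart, which a split can place on either side, so the arrays are not exchangeable. The labels do not say that replicates came from separate cultures, so splits of arrays cannot exclude a difference between cultures. For the differences of the corticosterone effect between times, the splits mixed corticosterone with vehicle within each time. The steroid effect itself thus enters those counts, and a split can turn a difference of 2 effects into a sum. Those splits therefore cannot test these differences, and chance is neither shown nor excluded. The 1 gene between 4 h and 2 h was reached in 14 splits (highest other 32). The 11 genes between 6 h and 2 h were reached in 16 (highest other 355). Between 6 h and 4 h the count was 0, which every split reaches, so it says nothing about chance (highest other 145).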

How the results depend on the processing

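The fits without the 2 arrays, normexp, the filter for brightness on all 36 arrays, the combination of weights with fewer arrays, and the counts of both against RU486 at single times were chosen after seeing the data, as was the fit of only the groups compared with unchanged response genes. Neqc, its offset, detection p-values as filters and the bead chip as a block were not run, because no label ties those columns to samples. Of 124 gene values chosen by the naming rule, 124 remained called with array weights, 118 without the 2 arrays and 79 with only the groups compared, and none turned. Over alternatives other than left-out arrays, 1357 of 1464 such values kept their call and 107 lost it. With 1 array left out, 1279 of 1560 kept it and 281 lost it. Lipa, Sgpl1 and Mex3a with corticosterone at 4 h lost it in all 6 such fits, and Xpr1 and Stk40 for both against RU486 over the times in all 18. Signal over background limits the folds of dim genes. For whole comparisons, values that left their side of the threshold, or counts of called genes that moved by more than 1.5 times, follow. Except where fewer arrays or genes are named, the cause was not tested.

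With array weights, corticosterone against vehicle gave 225 at 2 h, 6329 at 4 h, 1659 at 6 h and 5197 over times, and RU486 against vehicle gave 387 at 2 h, 6377 at 4 h, 356 at 6 h and 1827 over times. Both against vehicle gave 1 at 2 h, 6425 at 4 h, 3460 at 6 h and 4605 over times, and both against corticosterone gave 2708 at 2 h, 8353 at 4 h, 6132 at 6 h and 9109 over times. Both against RU486 gave 2274 at 2 h, 148 at 4 h, 5763 at 6 h and 4868 over times, and the interaction gave 7071 over times. RU486 against corticosterone gave 5042 over times, and the corticosterone effect gave 24 between 4 h and 2 h, 684 between 6 h and 4 h and 119 between 6 h and 2 h. Vehicle over time gave 5561. With array weights and without the 2 arrays that stand apart, corticosterone against vehicle gave 184 at 2 h, 6514 at 4 h, 1794 at 6 h and 5390 over times, and RU486 against vehicle gave 500 at 2 h, 6552 at 4 h, 383 at 6 h and 1933 over times. Both against vehicle gave 1 at 2 h, 6643 at 4 h, 3082 at 6 h and 4512 over times, and both against corticosterone gave 2804 at 2 h, 8469 at 4 h, 6370 at 6 h and 9204 over times. Both against RU486 gave 2559 at 2 h, 161 at 4 h, 5882 at 6 h and 5110 over times, and the interaction gave 7248 over times. RU486 against corticosterone gave 5196 over times, and the corticosterone effect gave 18 between 4 h and 2 h, 629 between 6 h and 4 h and 107 between 6 h and 2 h. Vehicle over time gave 5381.

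Without those 2 arrays and with equal weights, corticosterone against vehicle gave 128 at 2 h, 1672 at 4 h, 295 at 6 h and 2352 over times, and RU486 against vehicle gave 603 at 2 h, 759 at 4 h and 282 over times. Both against vehicle gave 1 at 2 h, 105 at 4 h, 0 at 6 h and 1233 over times, and both against corticosterone gave 1947 at 2 h, 3438 at 4 h, 847 at 6 h and 5906 over times. Both against RU486 gave 807 at 2 h, 386 at 6 h and 581 over times, and the interaction gave 3881 over times. RU486 against corticosterone gave 2330 over times, and the corticosterone effect gave 5 between 4 h and 2 h and 41 between 6 h and 2 h. Vehicle over time gave 3130, and the RU486 shift was 0.092 at 2 h, on 1744 genes chosen anew. Fitted on only the groups compared, and so on fewer arrays, corticosterone against vehicle gave 9 at 2 h, 2853 at 4 h, 0 at 6 h and 354 over times, and RU486 against vehicle gave 650 at 4 h and 1 over times. Both against vehicle gave 3619 at 4 h, 0 at 6 h and 15 over times, and both against corticosterone gave 904 at 2 h, 5796 at 4 h and 6 at 6 h. Both against RU486 gave 0 at 6 h and 154 over times, and RU486 against corticosterone gave 2117 over times. The corticosterone effect gave 0 between 4 h and 2 h and 0 between 6 h and 2 h, and vehicle over time gave 0. The ratio left under RU486 was 0.034 at 4 h. The RU486 shift was 0.082 at 2 h, 0.14 at 4 h and 0.011 at 6 h, and passed at 4 h only. At 4 h the ratio and the shift rest on the 9 genes called at 2 h, since 0 were called at 6 h. At 2 h and 6 h the shift rests mostly on the 2853 genes called at 4 h, so these values are not like for like. With unchanged response genes it was 0.081 at 4 h, now past the threshold, and it stayed past it at 2 h and 6 h.

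With no filter on dim probes, both against corticosterone gave 229 at 2 h and both against RU486 gave 1 at 2 h. With the 10103 genes brighter than the median on all 36 arrays, both against vehicle gave 4 at 6 h, and the corticosterone effect gave 0 between 4 h and 2 h and 2 between 6 h and 2 h. Vehicle over time gave 1086. When all probes were tested separately, both against RU486 gave 5 over times, and the corticosterone effect gave 2 between 4 h and 2 h. With an intensity trend and robust prior, corticosterone against vehicle gave 103 at 4 h, and RU486 against vehicle gave 1 at 6 h and 5 over times. Both against vehicle gave 0 at 6 h and 47 over times, and both against RU486 gave 15 at 6 h. After normexp with offset 16, both against vehicle gave 0 at 6 h and 54 over times, and both against RU486 gave 37 at 6 h and 5 over times. The corticosterone effect gave 0 between 4 h and 2 h and 3 between 6 h and 2 h. After normexp with offset 50, both against vehicle gave 5 at 6 h.

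With each array left out in turn, corticosterone against vehicle ranged from 10 to 74 at 2 h, 50 to 95 at 4 h, 97 to 4682 at 6 h and 356 to 1165 over times, and RU486 against vehicle ranged from 0 to 11 at 2 h, 0 to 22 at 4 h, 0 to 5330 at 6 h and 3 to 56 over times. Both against vehicle ranged from 0 to 1505 at 6 h and 31 to 576 over times, and both against corticosterone ranged from 33 to 90 at 2 h, 163 to 363 at 4 h and 90 to 359 at 6 h. Both against RU486 ranged from 0 to 5 at 2 h, 0 to 157 at 6 h and 0 to 5 over times, and the interaction ranged from 802 to 2181 over times. RU486 against corticosterone ranged from 230 to 485 over times, and the corticosterone effect ranged from 0 to 1 between 4 h and 2 h and 5 to 16 between 6 h and 2 h. Vehicle over time ranged from 699 to 7610, and the ratio left under RU486 ranged from -0.81 to 6.35 at 2 h and -0.97 to -0.054 at 6 h. The RU486 shift ranged from -0.041 to 0.24 at 2 h. The highest counts for corticosterone and for RU486 against vehicle at 6 h came without vehicle 6 h replicate 3. The RU486 shift at 2 h was -0.033 without vehicle 6 h replicate 2 and -0.041 without vehicle 6 h replicate 3, and the ratio was 1.66 and 6.35. These fits keep vehicle 6 h replicate 1, which stands apart. They call 3695 and 4682 genes for corticosterone at 6 h, from which response genes are drawn. With an intensity trend and robust prior the ratio at 6 h was -0.20, and with the genes called in the mean over times it was -0.55 at 2 h and -0.54 at 6 h.

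With an estimated correlation, 9 of the 39 list calls held and 30 were lost. With 1 array left out and the preset correlation, 319 list values kept their call, 57 lost it and 2 turned. Some lists turned direction, given here as signed -log10 p. Extracellular matrix genes with corticosterone at 6 h were at -0.40 with array weights, -0.14 without the 2 arrays and -0.45 with both choices. With 1 array left out they ranged from -0.035 without vehicle 6 h replicate 1 to 2.49 without vehicle 6 h replicate 2. Glucose and glycogen genes were at -0.040 without the 2 arrays and -0.21 with weights too for corticosterone at 6 h, and at -0.12 and -0.071 over the times. With RU486 at 6 h they were at -0.33 and -0.26. With 1 array left out they ranged there from -0.16 without vehicle 6 h replicate 1 to 3.29 without vehicle 6 h replicate 3.

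Same-numbered arrays deviated together in part at 2 h, where 15 of 18 pairs had a correlation above 0.1 (mean 0.256, against -0.113 for different numbers), and less at 4 h (3 of 18) and 6 h (8 of 18). The 3 pairs at 2 h at or under it are those of vehicle replicate 3, so between corticosterone, RU486 and both all pairs passed at 2 h. Since not every pair passed this mark and the labels name no shared source, the numbers were not taken to pair the arrays. Of 12 arrays each at 2, 4 and 6 h, 6, 3 and 4 correlated best with their own number, and with 3 numbers some do so by chance. At 6 h the correlations of same-numbered pairs ran from -0.785 to 0.782. Both extremes are pairs of vehicle with both compounds, groups that each hold 1 array that stands apart. With a replicate block within each time, RU486 against vehicle gave 43 over times, and both against vehicle gave 85 at 6 h and 170 over times. Both against corticosterone gave 224 at 2 h, and both against RU486 gave 39 over times, with a ratio left under RU486 of -0.61 at 6 h. With a replicate block over all times, RU486 against vehicle gave 1 at 6 h, and both against vehicle gave 26 at 6 h and 160 over times. Both against RU486 gave 17 over times. The other counts moved by no more than 1.5 times with these blocks.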

Other observations

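The test of the score as a covariate was chosen after the result was seen.

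In vehicle cultures, cell cycle genes and cholesterol synthesis genes were lower at 6 h than at 2 h by camera, both at adjusted p = 0.00949, and adjusted p = 0.806 and 0.763 with an estimated correlation. None of the 18 lists passed between these times without the 2 arrays. Among astrocyte genes, Gjb6, which forms gap junctions, was higher with corticosterone than with vehicle over the times by 1.65 (SE 0.17) and lower with both compounds than with corticosterone (-1.55, SE 0.17). Nr3c1, the glucocorticoid receptor itself, was at -0.18 (SE 0.10, limma adjusted p = 0.412) with corticosterone over the times.

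With the score as a covariate and without the 2 arrays, RU486 alone lay on the corticosterone side of vehicle by 0.12 at 2 h (limma fry, adjusted p = 0.000225), 0.13 at 4 h (adjusted p = 0.000225) and 0.18 at 6 h (adjusted p = 0.00106). Both compounds minus RU486 alone was at -0.10, -0.01 and -0.16 (adjusted p = 0.00877, 0.86 and 0.0081).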
